A study of Mus musculus with 5 samples.

How the data were processed

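RNA from 5 Neuro2A lines was hybridised to 1 Affymetrix mouse array each, after labelling as biotin cRNA per the labels. The deposited values are array signal intensities on a linear scale, made by the authors with MAS5 per the submitters' processing notes. The version is not given in the sources used here. The 2% trimmed mean of the deposited intensity was 500.0 on every array, so the arrays had been scaled to a common level before deposit, and no further normalization was applied in the main setting. MAS5 signals of dim probe sets vary strongly on the log scale, which is why a brightness filter was used. No detection calls were used here.

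Of 45101 probe sets, 64 controls (names starting with AFFX) were left out. Values were taken to log2 with no offset, and probe sets with a mean log2 signal over the 5 arrays at or above the median were kept, which is a signal of 40.5 and left 22519. Gene symbols came from the platform annotation. Of the remaining 45037 probe sets, 34945 had 1 symbol, 932 had several and 9160 had none listed. Probe sets with several symbols or none are given by their ID. Gene numbers of 34741 were found in a gene table of assembly GRCm38.p6, and 0 symbols needed updating. No coordinates are given, since no genome build belongs to the values.

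The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), 2 knockdown lines against 3 control lines, with 3 residual degrees of freedom, a median prior of 5.42 degrees of freedom and Benjamini-Hochberg adjustment over all kept probe sets at 0.05. A model with 3 groups gave each knockdown line against the controls and line 2 against line 1, where each knockdown line is assumed to vary like the controls. No batch or shared replicate number is in the labels. The labels do not say whether lines were grown side by side, so p-values of single probe sets measure the spread between these 5 arrays. Leaving out a knockdown line leaves 1 sample in that arm, which is then assumed to vary like the controls.

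Gene lists, 29 with 1053 entries and 643 measured members, were tested with camera (preset correlation 0.01) on each gene's kept probe set of highest mean signal, with at least 3 members, and with an estimated correlation and fry as alternatives. This probe set is 1434458_at for Fst and 1435867_at for Kdm7a, and not the probe sets past the threshold, so the lists count 0 members past it. With its preset correlation camera compares the genes of a list with all other genes, so its p-values do not measure the spread between arrays. The agreement of the knockdown lines was compared with 100 simulated pairs of unchanged lines. Each pair shared controls that were drawn anew as well, and each probe set was drawn on its own. Other pairings of the 5 arrays were counted over all 10.

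Named genes followed a rule fixed before the data were examined. It takes Kdm7a, Phf2, Phf8 and Fst whatever their values, and up to 15 genes each way past the threshold with both lines on one side of all controls. Where fewer pass, it fills up with genes at least 2-fold beyond every control line, ranked by that gap. It adds up to 4 members of each list past the threshold, or else the 1 with the largest change. For line 2 against line 1 it takes the 5 largest changes each way. Id1, Id2, Id3, Smad6, Tgfb2, Chgb, Dkk1, Isl1, Pmvk, Fdps, Acss2 and Srebf1, and the second Ngfr probe set, were chosen after their values were seen, as were Cavin2, Hdac9 and the genes of single lines in the closing section. Probe set 1440557_at, the 1 past the threshold for line 2, falls outside the rule since it has no symbol, and is given by its ID.

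The test was tried on simulated data of 22519 probe sets, 200 of them changed, with the control means and the spreads that limma estimated in the same fit. Each probe set was drawn on its own, so correlation between probe sets is not included. For knockdown against control the test recovered 54.0% of 2-fold, 98.0% of 4-fold, 98.0% of 8-fold and 94.0% of 16-fold changes in 1 draw. That draw had 195 calls, and the adjusted threshold is stricter where few probe sets pass. The shares thus do not carry over to the data, which gave 2 calls. There, Fst 1434458_at (log2 change -2.01, adjusted p = 0.113 in limma) and Zdbf2 (1.99, 0.0674) did not pass. Over 20 draws 10.4% of the calls in simulated data were unchanged probe sets, more than the intended share, against 3.38% without trend and robust. With nothing changed it made at least 1 call in 14 of 20 draws, and up to 7, against 1 of 20. The fit was kept as it had been fixed before the data were examined, and its p-values are too small by this measure.

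Alternatives fixed before the data were examined were quantile normalization, median centring, cyclic loess, no brightness filter, a filter at the 70th percentile, an offset of 32, eBayes without trend and robust, 1 probe set per gene, the mean over a gene's probe sets for the lists, array weights, an adjusted p under 0.10 and leaving out each array in turn. The activin, BMP and TGF-beta list without Fst, the lists without Id1 to Id4, and leaving out arrays for the single lines, the agreement and the 2-fold count were added after seeing the data.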

Results

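Gene expression was measured in 5 lines of Neuro2A, a mouse neuroblastoma cell line, with 1 Affymetrix 3' expression array per line. The study's purpose, as its design text gives it, was to examine what KDM7, the histone H3 lysine 9 and lysine 27 demethylase encoded by Kdm7a, does to gene expression. The control arm held 3 lines, namely parental cells (control replicate 1), cells with an empty vector (replicate 2) and cells with a vector against EGFP (replicate 3). The knockdown arm held 2 stable lines made with different vectors against KDM7. Each array carried 45101 probe sets, of which 22519 passed the brightness filter and were tested. The lines of an arm served as its replicates, so the spread holds differences between lines and constructs as well as between arrays, and no line was measured again. The labels do not say that the lines were cultured separately, so p-values of single probe sets measure only the spread between these arrays. List p-values from camera with its preset correlation compare the genes of a list with all other genes and do not measure that spread. The number of arrays, 3 against 2, limits the precision of every value. Log2 changes are knockdown minus control throughout, and errors are standard errors from limma unless named as SD.

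Kdm7a, the targeted gene, was lower in both knockdown lines than in every control line. Probe set 1456150_at had a signal of 588 ± 91.4 (SD, n = 3) in the control lines and 133 ± 3.93 (SD, n = 2) in the knockdown lines, 4.38-fold lower by mean log2 values (log2 change -2.13, SE 0.20). The single values were 487, 611 and 665 in the parental, empty vector and EGFP knockdown lines, and 130 and 136 in KDM7 knockdown lines 1 and 2. Probe sets 1435867_at (log2 change -1.99, SE 0.25) and 1427359_at (-1.86, SE 0.40) lay in the same direction. In limma, 1456150_at passed the threshold at an adjusted p of 0.0468, and the other 2 did not, at 0.128 and 0.869. The paralogs encode related demethylases. Phf8 had a log2 change of -0.29 (SE 0.21, adjusted p = 0.917 in limma), which was -0.09 without the parental line. Phf2 had 0.00 (SE 0.23) by probe set 1434924_at, a sign that turned under quantile normalization, median centring and cyclic loess, and 0.31 (SE 0.48) by the dimmer 1421069_at, with 0.03 without the parental line and 0.70 without the empty vector line. Neither paralog passed the test.

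**Figure D1:**
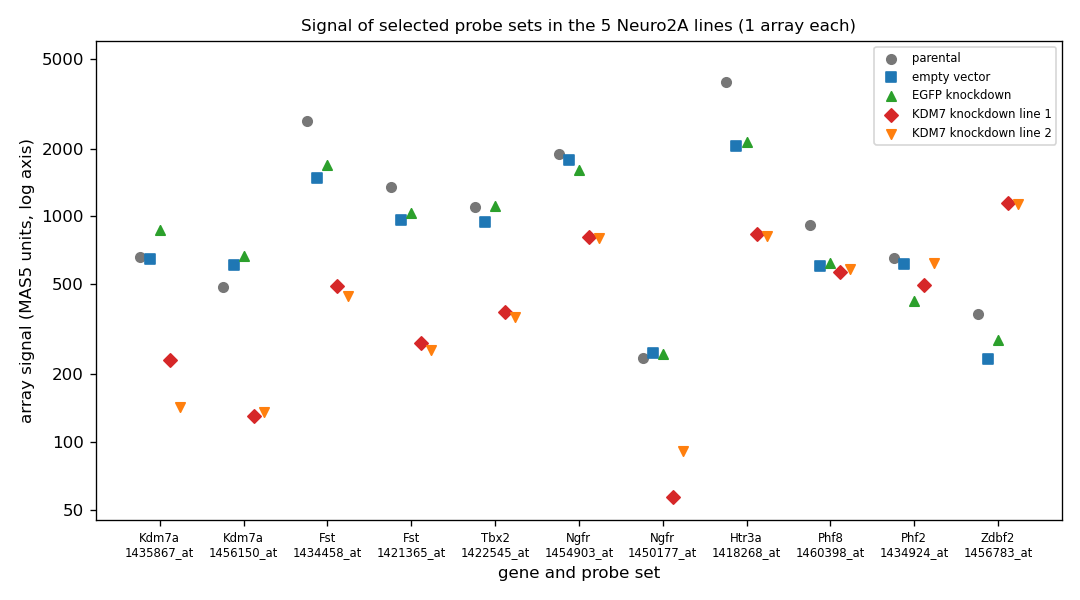
Signal of 11 probe sets on a log axis (MAS5 units), with 1 point for each of the 5 lines and 1 array per line. The probe sets of Kdm7a, Fst, Tbx2, Ngfr and Htr3a lie lower in the 2 KDM7 knockdown lines than in the 3 control lines, Zdbf2 lies higher at 1152 and 1141, Phf8 lies just below the controls, and Phf2 overlaps with them.

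The other gene past the threshold was Fst, which encodes follistatin, a secreted protein that binds activin and some bone morphogenetic proteins (BMPs). Its probe set 1421365_at had a signal of 1119 ± 202 (SD, n = 3) in the control lines and 264 ± 12.8 (SD, n = 2) in the knockdown lines, 4.19-fold lower (log2 change -2.07, SE 0.19, adjusted p = 0.0468 in limma). The second probe set of Fst, 1434458_at, had a log2 change of -2.01 (SE 0.24) and an adjusted p of 0.113. Tbx2, a T-box transcription factor, followed at 1055 in control and 366 in knockdown lines (log2 change -1.52, SE 0.16), and Zdbf2, a paternally expressed imprinted gene, at 294 and 1147 (log2 change 1.99, SE 0.22). Both had an adjusted p of 0.0674 in limma and did not pass.

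Across all 22519 probe sets limma called 2, both lower in the knockdown lines, 1 of Kdm7a and 1 of Fst. At an unadjusted p under 0.05 in limma there were 1117, or 4.96% of those tested, near the share this threshold gives with nothing changed. The parental and EGFP knockdown lines as the pair gave 2081, the parental and empty vector lines 1794 and the remaining pairings 580 to 769. Without the trend and robust options of the variance model limma called 0, with a smallest adjusted p of 0.722, and in simulated data of this design with nothing changed the fit used here made at least 1 call in 14 of 20 draws, against 1 of 20 without those options. Leaving out the empty vector line, the EGFP knockdown line, KDM7 knockdown line 1 or KDM7 knockdown line 2 ended both calls, with adjusted p in limma for Fst of 0.0884, 0.659, 0.187 and 0.449 and for Kdm7a of 0.0902, 0.659, 0.230 and 0.449, while both held without the parental line at 0.0365. Over the alternatives the called Fst probe set ranged from -2.18 to -1.92 and the second from -2.18 to -1.76. The called Kdm7a probe set ranged from -2.26 to -1.90, the brightest from -2.33 to -1.64, and the dimmest reached -1.06 with an offset of 32 added to the signal.

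A rule of size gave a wider set. Both knockdown lines were at least 2-fold beyond every control line for 25 probe sets, 7 above and 18 below. Of these, 6 named genes lay above and 12 below, and apart from Kdm7a and Fst none passed the test. Below the controls were Tbx2, Ngfr, the p75 neurotrophin receptor, and Htr3a, a subunit of a serotonin-gated ion channel. Ngfr 1450177_at had a signal of 243 in control and 73.7 in knockdown lines (log2 change -1.76, SE 0.27, adjusted p = 0.389 in limma), and its brighter probe set 1454903_at had 1755 and 808. Htr3a had a signal of 2726 in control and 831 in knockdown lines (log2 change -1.65, SE 0.27). Also below were Atoh8, a basic helix-loop-helix transcription factor (-2.56, SE 0.59), Susd5 (-1.84, SE 0.34, with -0.65 by a second probe set), Ttc39c (-2.74, SE 0.55), 4930524J08Rik (-2.75, SE 0.43) and Akain1 (-2.31, SE 0.65). Atoh8 had -1.64 without knockdown line 1. Myl9, a myosin light chain, had a log2 change of -4.90 with an SE of 1.83, since its signal was 2327 in the parental line and 40.1 and 56.9 in the other control lines, and it had -3.03 without the parental line. Ypel1 1431781_at had -1.94 (SE 0.40), while its probe set 1421048_a_at had 0.17. The mean knockdown signals of Atoh8, Ttc39c, 4930524J08Rik, Akain1 and Myl9 were 26.0, 18.6, 14.1, 29.9 and 6.11, and Ypel1 had 20.8 and 17.5 in the 2 lines, under the mean level of 40.5 at which probe sets were kept. These signals were not shown to be above background, so the sizes are uncertain, and with the offset of 32 the log2 changes were -1.51, -1.48, -1.44, -1.58, -2.70 and -1.05.

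Above every control line, besides Zdbf2, were Tgfbi, which encodes an extracellular matrix protein, Smarca1, a chromatin remodelling ATPase, Arntl2, Wsb2 and 1700094D03Rik. Tgfbi 1415871_at had a signal of 30.4 in control and 133 in knockdown lines (log2 change 2.18, SE 0.48), and its other probe sets had log2 changes of 1.06, 1.73 and 1.99. Smarca1 had a log2 change of 2.97 (SE 0.99) with control signals from 9.79 to 125. Its signals of 37.5 in the parental and 9.79 in the empty vector line were under 40.5, so the size is uncertain. With the offset of 32 its log2 change was 2.02. Arntl2 had 1.52 (SE 0.36), but 0.17 by a brighter probe set. Wsb2 1438129_at had 1.42 (SE 0.40), but its 2 brighter probe sets had -0.33 and 0.02. The mean control signals of Tgfbi 1415871_at and Wsb2 1438129_at were likewise under 40.5, and with the offset their log2 changes were 1.40 and 0.86. 1700094D03Rik 1429907_at had 1.25 (SE 0.27), and its other tested probe sets had -0.18 and -0.53. The count of 25 was not particular to the knockdown lines. Taking the parental and EGFP knockdown lines as the pair gave 40, and the parental and empty vector lines 35. Both knockdown lines lay on one side of all control lines for 22.8% of probe sets, where chance gives 20%. That share was higher for the parental and EGFP knockdown lines (25.8%) and the parental and empty vector lines (25.5%). It was 16.7% to 18.8% for the remaining pairings. The count was 978 with no brightness filter, 7 with the filter at the 70th percentile and 10 with an offset of 32 added to the signal.

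Of 29 gene lists fixed before the data were examined, 5 passed limma's camera test with its preset correlation of 0.01, 0 with an estimated correlation and 1, another list, with fry. The 5 include the list of KDM7 and its paralogs, which holds the targeted gene. Genes of activin, BMP and TGF-beta signalling were lower as a list (median log2 change -0.13, adjusted p = 1.48e-04 in limma camera). The list did not pass with an estimated correlation (adjusted p = 0.425 in limma camera) or with fry (adjusted p = 0.253). Both knockdown lines lay below every control line for 11 of its 34 measured members and above for 1. Over all probe sets 0 members rose and 0 fell by the probe set used for each gene, and adjusted over the list alone 4 fell, namely Fst, Id3, Smad6 and Tgfb2. Id3, an inhibitor of basic helix-loop-helix factors and a BMP target, had a log2 change of -1.57 (SE 0.36), Smad6, an inhibitory SMAD, -1.07 (SE 0.27), and Tgfb2, a ligand, -1.04 (SE 0.28). The other tested probe sets of Tgfb2 had -0.40, -0.76 and -0.92. Id1 had -0.65 (SE 0.18) and Id2 -1.36 (SE 0.45), or -0.91 without the parental line. The parental line had the highest signal of these genes, for example 4812 for Id3 against 2941 and 2006 in the other control lines, and without it the list had an adjusted p of 3.21e-04 in limma camera.

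Genes of cholesterol and fatty acid synthesis were higher as a list (median log2 change 0.27, adjusted p = 1.77e-05 in limma camera). The list did not pass with an estimated correlation (adjusted p = 0.655 in limma camera) or with fry (adjusted p = 0.605). Both knockdown lines lay above every control line for 15 of 30 measured members and below for 0. No single member passed, over all probe sets or adjusted over the list alone. Pmvk and Fdps, enzymes of the mevalonate pathway, had log2 changes of 1.01 (SE 0.26) and 0.43 (SE 0.12), Acss2, which makes acetyl-CoA from acetate, 0.70 (SE 0.17), and Srebf1, a transcription factor of lipid synthesis genes, 0.45 (SE 0.15). Scd1 1415965_at, a fatty acid desaturase, had 2.25 (SE 0.94), which came from line 2 with a signal of 542 against 58.3 in line 1 and was 0.65 without line 2. Line 1 lay below the EGFP knockdown line, at 68.0. The parental line had the lowest signal of the 4 genes named first, and the list had an adjusted p of 0.00105 in limma camera without it. Taking the parental and empty vector lines as the pair gave this list a camera p of 2.91e-06 for lower values, against 6.11e-07 for higher values in the knockdown lines.

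The other 3 lists past the threshold moved less or rested on few genes. KDM7 and its paralogs (3 genes, median log2 change -0.29) were lower at an adjusted p of 0.0138 in limma camera. With an estimated correlation this list had an adjusted p of 0.655, and with fry 0.253. Adjusted over the list alone 1 member fell, Kdm7a. As this is the targeted gene, the call of the list is no result beyond the knockdown itself. The paralogs Phf8 (log2 change -0.29, which is the list's median) and Phf2 (0.00) did not pass. Genes of the unfolded protein and amino acid response were higher by a median of 0.10 (adjusted p = 0.0157 in limma camera). With an estimated correlation their list had an adjusted p of 0.799, and with fry 0.858. Cytosolic ribosomal protein genes were higher by a median of 0.08 (adjusted p = 3.79e-04 in limma camera). With an estimated correlation theirs had an adjusted p of 0.799, and with fry 0.660. Of the unfolded protein and ribosomal lists 0 members passed. Median centring used the medians of all probe sets, dim ones included, and moved all changes alike by -0.11. This took the ribosomal median to -0.03 and left its distance to the median of all genes at 0.05. That distance was 0.0050 after quantile normalization and 0.06 after cyclic loess. Atf3, a stress-induced transcription factor, had a log2 change of 0.55 (SE 0.29), which was 0.30 without the parental line and 0.29 without knockdown line 1. It was at 658 in the empty vector line, above knockdown line 2 at 576. Rps27 1460699_at had 0.63 (SE 0.46). Rps27 was at 1103 in line 2 and 341 in line 1, within the control range of 331 to 462, and its sign turned without line 2. With the preset correlation, the ribosomal list did not pass after quantile normalization (adjusted p = 0.454 in limma camera) or median centring (0.884), without trend and robust (0.161) or without the empty vector line (0.0996). It passed in the other alternatives, down to 1.59e-08 without the EGFP knockdown line. The unfolded protein list did not pass after median centring (0.350), without trend and robust (0.177), without the parental line (0.388) or without knockdown line 1 (0.162). The KDM7 list did not pass without the parental line (0.139) or the empty vector line (0.0516). Other pairings of the 5 arrays also gave list calls, 6 for the parental and EGFP knockdown lines as the pair and 5 for the parental and empty vector lines.

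**Figure D2:**
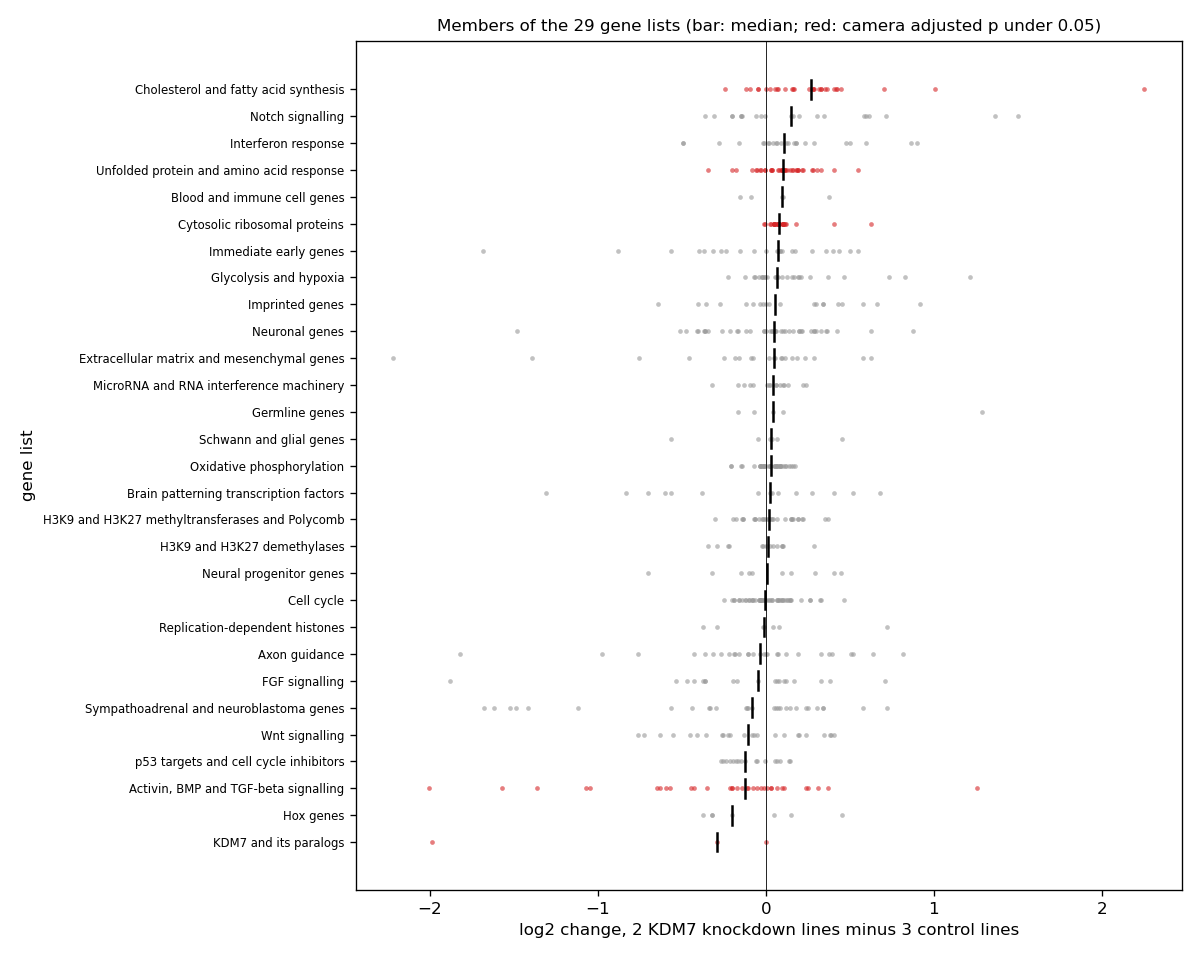
Members of the 29 gene lists, each point 1 gene by its log2 change (2 KDM7 knockdown lines minus 3 control lines), with the list's median as a bar and the 5 lists past an adjusted p of 0.05 in limma camera in red. The cholesterol and fatty acid list has the highest median, 0.27, and the list of KDM7 and its paralogs, which holds the targeted gene, the lowest, -0.29.

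The remaining 24 lists had adjusted p from 0.0760 to 0.959 in limma camera. The lowest was that of sympathoadrenal and neuroblastoma genes (29 measured), in which, adjusted over the list alone, Tbx2 and Ngfr fell and Chgb, a granin of secretory vesicles, rose (log2 change 0.58, SE 0.13, or 0.38 without knockdown line 2). In this list Gata3 had -1.68 (SE 0.46) and Isl1 -1.62 (SE 0.55, with -1.03 by a second probe set), but both were also low in the empty vector line. Gata3 was at 224 there against 554 and 585 in the other controls and 178 and 95.3 in the knockdown lines, and Isl1 at 545 against 1493 and 1998 in the other controls. Dkk1, a secreted Wnt inhibitor, fell adjusted over the Wnt list alone (log2 change -0.72, SE 0.15), as did Meis1, a homeobox gene, over the list of brain patterning factors (-1.31, SE 0.26). In 11 of the 24 lists the median, the mean and the test differed in sign.

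By subject, the median log2 changes of these lists were as follows, each with its adjusted p in limma camera. Among chromatin genes they were 0.01 for H3K9 and H3K27 demethylases (0.706), 0.02 for the methyltransferases and Polycomb (0.959) and -0.01 for replication-dependent histones (0.714). Among signalling genes they were -0.05 for FGF (0.311), -0.11 for Wnt (0.244) and 0.15 for Notch (0.689). The neural lists had 0.05 for neuronal genes (0.585), 0.01 for neural progenitor genes (0.959), -0.08 for sympathoadrenal genes (0.0760), -0.04 for axon guidance (0.463) and 0.02 for brain patterning factors (0.244), and the Hox genes had -0.20 (0.385). Growth and stress lists had -0.0033 for the cell cycle (0.958), -0.12 for p53 targets (0.211), 0.11 for the interferon response (0.463) and 0.07 for immediate early genes (0.837). Metabolic lists had 0.07 for glycolysis and hypoxia (0.165) and 0.03 for oxidative phosphorylation (0.679). The first of these was the 1 list to pass with fry, at an adjusted p of 0.0401. Imprinted genes had 0.05 (0.689), germline genes 0.04 (0.745) and microRNA machinery 0.04 (0.958). Lists that would mark other cells had 0.05 for extracellular matrix and mesenchymal genes (0.958), 0.03 for Schwann and glial genes (0.958) and 0.10 for blood and immune genes (0.959). With the preset correlation and without the EGFP knockdown line, the matrix list turned to lower at an adjusted p of 0.0304 in limma camera. The sympathoadrenal list was lower and passed there too, at 0.0304, and with the filter at the 70th percentile, at 0.00888. In the FGF list the median log2 change was -0.15 in knockdown line 1 and 0.06 in line 2. With an estimated correlation and all arrays, the adjusted p in limma camera was 0.967, 0.655 and 0.843 for these lists in turn.

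In these lists the member with the largest absolute log2 change did not pass over all probe sets. Cxcl10, an interferon-induced chemokine, had 0.90 (SE 0.37, or 0.56 with the offset), H3c4 0.72 (SE 0.38) and Phf1 0.37 (SE 0.21). Cntn2, a neuronal cell adhesion gene, had -1.48 (SE 0.35) but -0.42 by a second probe set. Nes, which encodes nestin, had -0.70 (SE 0.29) and -1.33 by a second. Lin28a had -0.32 (SE 0.15) and -0.54 by a second, and Uqcrc2 of respiratory complex III -0.21 (SE 0.08), or -0.32 after median centring, but -0.02 by another. Mfng, a Notch-modifying glycosyltransferase, had mean signals of 76.9 in the knockdown and 34.8 in the control lines, but line 1 at 69.8 lay below the EGFP knockdown line at 70.4, and with the offset the log2 change was 0.80.

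The values of other such members moved by over 1.5 times when 1 array was left out. The parental line set much of the change of Acta2 (-2.22, SE 1.69, or -0.56 without it), Aldoc, a glycolytic aldolase (1.21, SE 0.71, or 0.47), and Flrt3 of the FGF list (-1.88, SE 0.88, or -1.12). Flrt3 was at 22.4 in the empty vector line, between the knockdown lines at 23.0 and 21.7. The same held for Vav1 (0.38, SE 0.45, or 0.05) and Cdkn2d (-0.26, SE 0.17, or -0.12). The EGFP knockdown line set that of Ccnd3 (0.47, SE 0.40, or 0.02 without it) and Sohlh2 (1.29, SE 1.26, or 0.02; 1.96 without the parental line). Kdm4c had -0.34 (SE 0.25), which was -0.13 without the empty vector line and -0.20 without knockdown line 1. Dcc, a netrin receptor, had -1.82 (SE 0.77), with -3.28 without line 1 and -0.36 without line 2. Nr4a3 had -1.68 (SE 0.68), with -0.83 without line 1 and -2.54 without line 2, and Egr2 -0.57 (SE 0.51), with -1.38 and 0.25. Hoxc8 had 0.45 (SE 0.35) and 0.28 without line 1. Wnt5a had -0.76 (SE 0.30), with -0.49 without line 2 and -0.48 by a second probe set. Igf2 had 0.92 (SE 0.57), with 0.45 without the empty vector line, 1.41 without line 1 and 0.42 without line 2. Mean knockdown signals of Flrt3, Dcc and Nr4a3 were 22.4, 33.5 and 27.7, so these sizes are uncertain too, with -1.21, -0.85 and -0.94 with the offset. At least 1 control line also lay within or beyond the range of the knockdown lines for Acta2, Ccnd3, Sohlh2, Vav1, Kdm4c, Nr4a3, Egr2, Hoxc8, Wnt5a, Igf2 and H3c4.

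Each vector was also set against the controls alone. Each knockdown line is 1 array here, the spread comes from the 3 control lines alone, and each line is assumed to vary like them, so these values have no replicate check and compare single arrays. In limma's model with 3 groups, 0 probe sets passed for knockdown line 1, with a smallest adjusted p of 0.136 and 449 at an unadjusted p under 0.05, and 1 passed for knockdown line 2, with 623. Kdm7a 1456150_at had log2 changes of -2.16 (SE 0.30) in line 1 and -2.10 (SE 0.30) in line 2, and Fst 1421365_at -2.02 (SE 0.28) and -2.12 (SE 0.28). The probe set past the threshold in line 2 was 1440557_at, which has no gene symbol here. Its signal was 24.8 in line 2 and 607 in line 1, with 642, 768 and 716 in the control lines. The signal of 24.8 is under 40.5 and not shown to be above background, so the size is uncertain. It was also the 1 probe set past the threshold between the arrays of the 2 knockdown lines (line 2 minus line 1 -4.61, SE 0.34, adjusted p = 0.0128 in limma, or -3.49, SE 0.31 and 0.0461 with the offset of 32). That difference did not pass with no brightness filter, and neither it nor the call for line 2 passed without the EGFP knockdown line. Without the empty vector line the counts were 2 for line 1, 5 for line 2 and 2 for line 2 against line 1.

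The changes of the 2 knockdown lines against the control mean correlated across probe sets at r = 0.486, where probe sets are not independent replicates. Since both changes use the same 3 controls, unchanged lines and the controls they share were both drawn anew around the control means. This gave a mean r of 0.251 over 100 draws, at most 0.297. Each probe set was drawn on its own, so the simulated ranges may be too narrow for correlated probe sets and the excess overstated. The covariance was 0.0793 against a simulated 0.0417. Both lines were at least 2-fold above the control mean for 117 probe sets and below for 73, where the simulated means were 47.8 and 47.4 and independent lists of those lengths would share 4.47 and 3.98. The highest simulated counts were 64 and 65. Opposite changes of that size were found for 5 probe sets, with 24.5 simulated. Against the empty vector and EGFP knockdown lines alone, r was 0.462 with 0.333 simulated, and the covariance 0.0722 with 0.0470. Both lines were then 2-fold above for 105 probe sets, where at most 56 were simulated. The 52 below and 9 opposite lay within the simulated ranges of 24 to 58 and 5 to 17, so the excess of shared lower probe sets and the lack of opposite ones did not hold without the parental array. Against the empty vector and EGFP knockdown lines, each knockdown line's own counts also exceeded the simulated ones. Line 1 had 273 above and 270 below, with at most 254 and 245 simulated. Line 2 had 290 above and 325 below, with at most 255 and 250. Part of the excess above may thus come from a simulated spread that was too small and not from agreement. The 3 controls cannot be split into parts of 2 lines, so part of the excess may also come from the shared controls.

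**Figure D3:**
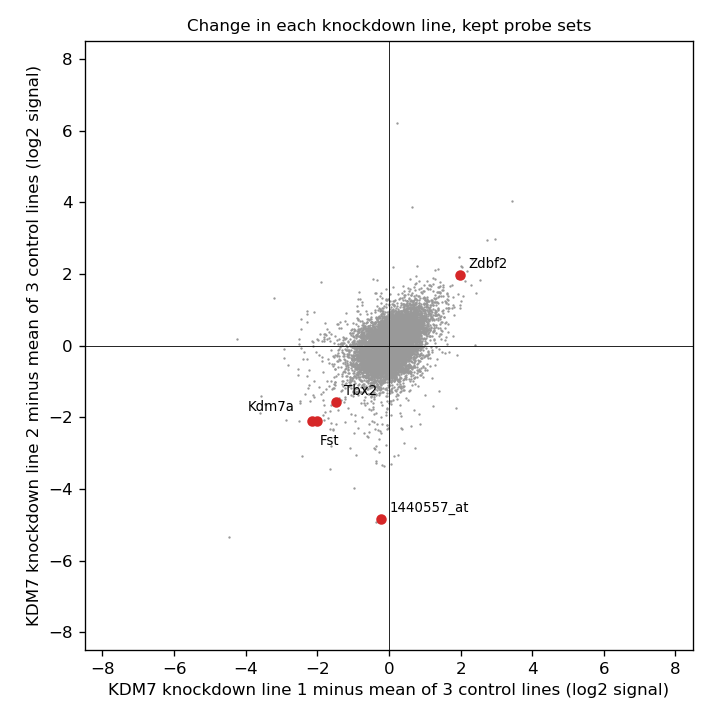
Log2 change of KDM7 knockdown line 1 (x axis) and line 2 (y axis) against the mean of the 3 control lines, each point 1 of 22519 probe sets. Kdm7a, Fst and Tbx2 lie low in both lines, Zdbf2 lies high in both at 1.99 and 1.98, and 1440557_at is low in line 2 alone at -4.83.

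The control lines differed among themselves. These differences were counted and not tested. The parental and empty vector lines were at least 2-fold apart for 1615 probe sets, the parental and EGFP knockdown lines for 1755, and the empty vector and EGFP knockdown lines for 1072. The 2 KDM7 knockdown lines were 2-fold apart for 693. The parental array stood apart from the rest, with correlations of log2 signal across probe sets of 0.964 to 0.968, against 0.976 to 0.983 among the other lines. The ratio of 3' to 5' signal for Actb, a sign of RNA and labelling quality, was 1.25 in the parental line, 1.43 in the empty vector line and 1.35 in the other lines.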

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

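The runs without the parental array and with other scalings had been fixed before the data were examined. Their use here to weigh explanations was chosen after the result was seen. The tests of the pairings of arrays for the 2 calls and of brightness with correlation between genes were chosen after it too. Probe set 1440557_at, with no gene symbol here, had a signal of 24.8 in knockdown line 2 and 607 in line 1, a log2 difference of -4.61 (SE 0.34, adjusted p = 0.0128 in limma). The lower signal is under the filter's level of 40.5 and not shown to be above background, so the size is uncertain, and it was -3.49 (SE 0.31, adjusted p = 0.0461 in limma) with an offset of 32. Each line is 1 array and the spread comes from the 3 control lines alone, so this has no replicate check and compares 2 arrays, not 2 vectors. No explanation was tested.

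The activin, BMP and TGF-beta list was lower in both knockdown lines. It had an adjusted p of 3.209e-04 in limma camera without the parental array, so the call did not rest on that array alone. After quantile normalization it had 2.474e-04 and after cyclic loess 1.89e-04, so the call did not depend on these scalings. These values use the preset correlation, with which other pairings of the arrays also gave list calls. They therefore bear on the call and not on its cause. Of the 10 pairings of the 5 arrays, 1 had a camera p as small, the real one at 1.02e-05 with 9.75e-04 as the next, but 10 pairings are too few for a share under 0.05. Reduced KDM7 stays open as a hypothesis, as do differences between lines, with 1 array each. The adjusted p ranged from 1.16e-05 to 0.425 over the alternatives, the highest in limma camera with an estimated correlation. That correlation was -0.0123, below the preset 0.01, so it does not account for the higher p. With an estimate, camera takes its degrees of freedom from the 5 arrays and not from the genes.

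The ribosomal list was higher by a median of 0.08 (SD of members 0.12), with an adjusted p of 3.79e-04 in limma camera and 0.799 with an estimated correlation. A trend with brightness stays open: the median lay at percentile 98.7 of 10000 random lists matched on signal, but these take genes as independent, and with the list's estimated correlation of 0.383 their range widened to -0.09 to 0.14, which holds it. Array scaling cannot be told apart from a change of these genes, since the adjusted p in limma camera was 0.4543 after quantile normalization but 1.89e-04 after cyclic loess. The distance of the list's median to that of all genes was 0.05 as deposited, 0.0050 and 0.06 in turn. Median centring shifts every gene alike and left the distance at 0.05, but the list then had an adjusted p of 0.884 in limma camera. That centring used the medians of all probe sets, including those the filter removed, which were 5.37 to 5.62 in log2 over the arrays. The medians of the kept probe sets were 8.62 to 8.64 as deposited. The call thus depends on the level to which the arrays are scaled, which in median centring was set with the dim probe sets included. Of the 10 pairings, 3 gave a camera p as small. The real one had 3.92e-05, the parental and empty vector lines 1.81e-10 and the EGFP knockdown line with KDM7 knockdown line 1 had 1.79e-05. A camera p this small was thus not particular to the knockdown lines. Even a single such pairing among 10 could not give a share under 0.05, and reduced KDM7 stays open.

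For the 2 probe sets past the threshold, 2 of the 10 pairings gave as many, the real one with 2 and the parental and EGFP knockdown lines with 12. A count this large was thus not particular to the knockdown lines, and 10 pairings are too few for a share under 0.05 in any case. The pairing with 12 calls points to a structure of the samples other than KDM7 knockdown, and reduced KDM7 and differences between lines both stay open.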

How the results depend on the processing

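The leave-one-out values for single lines, for the 2-fold count and for the agreement of the lines, and the lists without Fst or without Id1 to Id4 (5 lists each), were chosen after seeing the data, and the others before. Of 954 recomputed log2 changes of 64 named probe sets, 943 kept their sign, and of 491 list results 448 kept their direction. Part of the 943 was fixed in advance and is no sign of robustness. The brightness filters, eBayes without trend and robust, 1 probe set per gene and the adjusted p under 0.10 cannot alter a log2 change. Where no cause is named below, the cause was not tested. The 2 calls for KDM7 knockdown became 1 with median centring, 0 with cyclic loess, 0 with an offset of 32, 0 without trend and robust, 0 with 1 probe set per gene, 6 with array weights and 4 at an adjusted p under 0.10, and 0 to 4 leaving out 1 array. Without the parental line the 4 were Kdm7a, Zdbf2 and both Fst probe sets, without the empty vector line the 1 was Cavin2, without knockdown line 1 it was 1440557_at, and without the EGFP knockdown line or line 2 there were 0. Median centring, on the medians of all probe sets with dim ones included, moved the median log2 change of the kept ones by -0.11. With it the share of lower probe sets at an unadjusted p under 0.05 in limma went from 47.9% to 79.8%. That share was 54.4% with quantile normalization and 56.4% with cyclic loess. No paired analysis was possible because replicate numbers only name lines, and no number marks a shared culture or batch. For line 1 the count was 0 to 2 leaving out 1 control. For line 2 it was 2 with the filter at the 70th percentile and 0 to 5 leaving out 1 control. For line 2 against line 1 it was 0 with no filter and 0 to 2 leaving out 1 control. The 25 probe sets beyond every control line became 978 with no filter, 7 with the filter at the 70th percentile, 10 with the offset, and 48 (without the parental line) to 170 (without line 1) leaving out 1 array, where fewer arrays make the rule easier to meet. It was 107 without the empty vector line, 92 without the EGFP knockdown line and 136 without line 2. The correlation of the lines (0.486), judged by the spread of the simulated ones, was 0.4674 with quantile normalization, 0.2778 with no filter, 0.609 at the 70th percentile, 0.511 with the offset and 0.4624 to 0.5972 leaving out 1 control. Probe sets 2-fold apart were, for parental against empty vector, parental against EGFP knockdown and empty vector against EGFP knockdown, 13599, 13880 and 12562 with no filter, 392, 350 and 198 at the 70th percentile, and 819, 874 and 470 with the offset. The 5 lists became 0 with an estimated correlation, 1 with fry, 3 with median centring, 3 without trend and robust and 3 to 7 leaving out 1 array (3 without the parental line and 3 without the empty vector line).

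Directions turned as follows, below the threshold unless said. Phf2 1434924_at was -0.007739 with quantile normalization, -0.108 with median centring, -0.01136 with cyclic loess, and -0.1946 (without the EGFP knockdown line) to 0.1641 leaving out 1 array. Leaving out 1 array, Egr2 was -1.383 to 0.2509 and Rps27 -0.2189 to 1.473, both turned without line 2. Other probe sets gave -0.1771 and -0.5301 for 1700094D03Rik, -0.3273 for Wsb2 and 0.1724 for Ypel1. Of the lists, with adjusted p, those of methyltransferases and Polycomb (0.8813), cell cycle (0.8576), Schwann and glial, germline, and microRNA genes (0.9773 each) turned with fry. Neural progenitor (0.8489) and Schwann and glial genes (0.7753) turned with the mean over probe sets. With quantile normalization the methyltransferase and matrix lists (0.9925 each) and the neural progenitor, cell cycle and blood lists (0.9645 each) turned. With median centring oxidative phosphorylation (0.3497), immediate early (0.9626) and Schwann genes (0.8844) turned. With cyclic loess the cell cycle and blood lists (0.9643 each) turned. With no filter neural progenitor genes (0.8214) and Schwann, imprinted and germline genes (0.7237 each) turned. At the 70th percentile immediate early (0.9488) and Schwann genes (0.8605) turned. Without trend and robust the methyltransferase (0.9308), neural progenitor (0.9772) and matrix lists (0.9318) turned. Leaving out 1 array, which turned some lists, gave adjusted p of 0.5055 to 0.9631 for cell cycle, 0.06604 to 0.8232 for interferon, 0.6582 to 0.9949 for blood, 0.3108 to 0.9949 for germline, 0.8232 to 0.9949 for neural progenitor, 0.1643 to 0.8194 for immediate early, 0.4652 to 0.9122 for Schwann, 0.1393 to 0.8828 for imprinted, 0.7938 to 0.9793 for microRNA, 0.4513 to 0.9949 for methyltransferase and 0.1173 to 1 for histone genes. FGF genes ranged from 0.009964, lower and past the threshold without line 2, to 0.9793, turned without line 1. The matrix list ranged from 0.03037, turned and past the threshold without the EGFP knockdown line, to 0.864. Signal over background was not measured here, so how far it limits the dim probe sets is unknown.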

Other observations

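Both tests of hypotheses in this part were chosen after related values had been seen. Single lines carried their own genes, with 1 array each, and these differences were not tested. The parental line was at least 2-fold above all 4 other lines for 127 probe sets and below for 358, more than the 10 to 20 above and 64 to 128 below in the other lines. It was high in Acta2, a smooth muscle actin, and Myl9, with signals of 2733 and 2327 against at most 105 and 56.9 elsewhere, and in Tspan2 (1048), Timp2 (1146) and Glipr1 (833). Its Mycn 1425923_at was at 65.3 against 587 to 1413, while Mycn 1417155_at was at 1068 against 632 to 838, so the probe sets disagree. Anxa4 was at 76.9 against 418 to 642.

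The empty vector line was high in Cxcl1, a chemokine (869, with 197 as the next), and low in Gpm6b, a myelin-related membrane protein (34.1, with 444 as the next), and Nsg1 (45.5). The EGFP knockdown line was low in Sohlh2, a germ cell transcription factor (94.2 against 1244 to 1378), and high in Vav3 (621) and Lix1 (2451). Knockdown line 2 was high in Scd1 1415964_at, at 1864 against 85.6 or less, and knockdown line 1 low in Panx1, a channel protein, at 18.1 against 227 or more. The parental and EGFP knockdown lines shared high Cavin2 1416778_at (4311 and 3463 against 477 to 613), Hdac9 (711 and 761 against 153 to 209) and Isl1 (1493 and 1998 against 316 to 545).

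Less follistatin may leave more activin free, in which case SMAD2/3 target genes would rise. A list of 30 such genes, compiled after single values including those of Tgfbi and Acta2 had been seen, had 15 measured, 4 of them also in the activin, BMP and TGF-beta list. Its median log2 change was -0.07 with a camera p of 0.628 in limma. With a median near 0 over members that went both ways, this leaves the question open. A list of BMP target genes was also compiled and tested, but after Id1, Id2, Id3 and Smad6 had been seen to be low, and its value is not given since the test ran on genes chosen for the pattern. A loss of a demethylase of repressive marks may leave more genes lower than higher. At an unadjusted p under 0.05 in limma there were 1117 probe sets, against 580 to 2081 in the other pairings. These 1117 were 4.96% of those tested, near the share this threshold gives with nothing changed. Their direction thus cannot decide the question. Of them, 47.9% were lower, where the highest of the other pairings had 67.2%. The share was 54.4% after quantile normalization, where the highest other had 57.7%, and 56.4% after cyclic loess, where it was 61.6%. It was thus the largest of the 10 pairings in none of these, which gives the hypothesis no weight, but it lay on both sides of 50% and a larger share in another pairing does not exclude it, so the question stays open. Median centring shifts every gene alike, so its shares of 79.8%, with 92.4% as the highest other, decide nothing.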
